A study of Mus musculus with 8 samples.

How the data were processed

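Gene expression was measured in whole lungs of 8 mouse embryos at embryonic day 14.5, with 1 array per embryo. In 4 embryos the Shh-cre driver had been combined with 2 floxed copies of Ezh2, the gene of the histone methyltransferase of the Polycomb repressive complex PRC2, a combination meant to delete the gene in the lung epithelium. The 4 control embryos carried Shh-cre without the floxed alleles. The embryos came from 4 litters of 2, and each litter held a single genotype. Per the labels' protocols, lungs were kept in RNAlater and frozen, total RNA was extracted on columns, and 100 ng was copied from a poly(T) primer carrying a T7 promoter and amplified into biotin-labelled RNA for a 1-colour Affymetrix array.

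The deposited values are log2 expression per probe set, which per the submitters' processing notes were made with RMA in the package oligo. RMA corrects the background, normalizes between arrays and summarizes the probes of each probe set. The versions and options of these steps are not given in the sources used here. RMA makes the arrays' distributions alike, so a change shared by most genes would not be visible in these values, and it draws changes of dim genes towards 0. The table came with no detection calls, so a low value is not read as absence of a transcript. The arrays had median log2 values of 7.05 to 7.12 and correlated with one another at 0.9915 to 0.9976. For arrays, their number limits the precision.

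Of the 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 were not listed there. The annotation can be old. Of the single names, 23328 were found by gene number in a RefSeq table of the assembly GRCm38.p6, which updated 0 symbols and served only for names and for which genes neighbour each other. Each gene was represented by its probe set with the highest mean over the 8 arrays, which gave 22180 genes. More than 1 probe set was present for 1082 genes.

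Mutant and control lungs were compared with limma 3.58.1 in R 4.3.3. A linear model with genotype was fitted to the log2 values of each gene, with litter as a random block (consensus correlation 0.153), followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over the 22180 genes. Tests were two-sided and the threshold was an adjusted p of 0.05. Littermates share a dam, and no litter held both genotypes, so litter could not enter as a fixed block. It entered as a random block, and as litter means in an alternative. The embryos are separate animals. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

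The choice of tests, the 40 gene lists and the rule for naming genes were made before the data were examined. The lists hold cell type markers, pathways and complexes of the developing lung, Polycomb targets, and markers of tissues that a dissected lung could carry. Of their 1137 memberships, 84 were not tested. Each list was compared with all other genes by limma's competitive test camera with a preset correlation of 0.01 on values with the litter correlation removed, with Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated per list and the rotation test fry were alternatives. Named genes are a preset group, the 12 genes with the largest change in each direction whose groups did not overlap, and up to 4 members of each list. Predicted gene models, clones, genes named by accession, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors, and Xist, Tsix and Y-linked genes were left out of the largest changes. The preset gene Krt5 was not analysed here, and another preset item is not reported here.

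The fit was tested on simulated data with the real gene means and spreads, a litter correlation of 0.15 and 200 changed genes among 22180, in 10 draws. On average 45.2% of genes changed 1.25-fold were called (36 to 52% over the draws), 87.4% of those changed 1.5-fold (78 to 98%), 99.4% of those changed 2-fold and 100% of those changed 3-fold. False calls made up 9.07% of calls on average (6.77 to 19%), above the 5% that the adjustment aims at. The estimated litter correlation in these draws averaged 0.0389 (0.0342 to 0.0465), below the simulated 0.15 and below the 0.153 estimated from the data. The litter effect in the data may therefore be stronger than the simulated one, and the share of false calls higher. Of 100 unchanged lists per draw, 1.8% on average had an unadjusted p under 0.05 by camera. A list shifted by 0.3 was called in 10 of 10 draws. Genes were drawn independently of each other, so these draws do not test lists whose genes vary together. In the data the correlation estimated per list reached 0.36 (hypoxia) and was 0.064 for the p53 and Hox lists, against the preset 0.01.

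Alternatives covered the treatment of litters, each embryo or litter left out, a filter on dim genes, other scalings, other rules for several probe sets, the variance prior, array weights, the Xist level as a covariate for sex and other thresholds. Leaving out the arrays of control 3 and mutant 3, and using only embryos with a high Xist value, were added after the data had been seen.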

Results

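Log2 expression was compared between lungs of 4 embryos labelled as lacking Ezh2 in the epithelium and 4 Shh-cre control embryos, all at embryonic day 14.5. The comparison asks which genes differ in the lung between these genotypes, and PRC2 activity was not measured. Whole lungs were used, so each value averages epithelium with mesenchyme, vessels and other cells. Control 1, control 2 and mutant 3 had low Xist values (6.37 to 6.74) and high values of Y-linked genes. The other 5 embryos had high Xist values (12.61 to 13). By these genes 2 of 4 controls and 1 of 4 mutants were male. Both male controls came from litter 1 and both others from litter 2, so among controls sex and litter cannot be told apart. Control 3 and mutant 3 lay at opposite ends of the first principal component, which held 32.5% of the variance. No pair of arrays held the same values.

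Ezh2 itself differed little in whole lung. Its log2 value was 11.87 ± 0.05 (SD, n = 4) in controls and 11.78 ± 0.02 (SD, n = 4) in mutants. The log2 change was −0.09 ± 0.05 (SE), with an adjusted p of 0.652 by limma with Benjamini-Hochberg adjustment. All 4 mutants lay below all 4 controls, for which the two-sided exact permutation p was 0.0286, the smallest that 4 against 4 can give, with littermates taken as independent. Which probes of this probe set lie in the floxed exons is not known here, and cells in which the Cre driver is not active add to the signal, so the gene is a weak check of the labels. The log2 changes of Ezh1, the paralogue of Ezh2, and of the PRC2 subunits Eed and Suz12 were 0.06, −0.06 and −0.10, and none passed the test. None of the 12 measured PRC2 genes and none of the 18 measured PRC1 genes passed.

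In mutant lungs, 134 genes rose and 55 fell among the 22180 tested. Among the genes covered by the naming rule, the largest increases were in Tbx15, a T-box transcription factor, with a log2 change of 2.48 ± 0.17 (SE), Cbr2, a carbonyl reductase of club cells, with 2.26 ± 0.09, Cdkn1a, which encodes the cell cycle inhibitor p21, with 2.24 ± 0.08, and Krt15, a keratin of basal cells, with 2.04 ± 0.13. They were followed by Anxa8 (log2 change 1.64), Eda2r (1.40), Dglucy (1.34), Dapl1 (1.28), Adamtsl3 (1.27), Hoxb9 (1.26), Krt4 (1.22) and Krt17 (1.17). The largest decreases under the same rule were in Cym, the gene of chymosin, which fell by 1.78 ± 0.25 on the log2 scale, Tinag, which fell by 1.17 ± 0.07, and Zfp804b, which fell by 1.14 ± 0.19. Cpn1, a carboxypeptidase subunit, fell by 0.94, Zfp868 by 0.89, Elapor1 by 0.84, Cckar, a cholecystokinin receptor, by 0.83 and Veph1 by 0.79. Fmod, which encodes the matrix proteoglycan fibromodulin, fell by 0.70, and Entpd1, Aldh1a7 and Adamts18 fell by 0.69, 0.68 and 0.65. The rule left out 18 called genes, among them Gm53, Mir196a-1 and 2900092D14Rik, which rose by 1.87, 1.69 and 1.41 on the log2 scale, and Gm19990 and D5Ertd579e, which fell by 1.00 and 0.87, all named here after their values were seen.

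These counts come from limma with Benjamini-Hochberg adjustment at an adjusted p of 0.05, and 2189 genes had an unadjusted p under 0.05. The adjusted p was 2.28e-07 for Cdkn1a, 5.99e-07 for Cbr2, 4.34e-05 for Tbx15 and 2.87e-05 for Krt15 by limma with Benjamini-Hochberg adjustment. Of the genes that rose 21 changed at least 2-fold, and of those that fell 3 did. In all 189 called genes the groups did not overlap. Over all genes this held for 8.07%, against 2.86% by chance with embryos taken as independent. With the 2 littermates averaged, 65 genes were higher and 33 lower. Without mutant 4 the counts were 73 and 28, and without control 4 they were 89 and 32. The excess of increases also varied. With the Xist level as a covariate and the litter block kept, the counts were 361 and 313. They were 98 and 90 without litter 1, 175 and 43 without litter 2, and 79 and 71 among embryos with a high Xist value. The fits without a litter or with only high-Xist embryos had no litter block and took littermates as independent. Dropping the block alone gave 190 and 95.

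**Figure D1:**
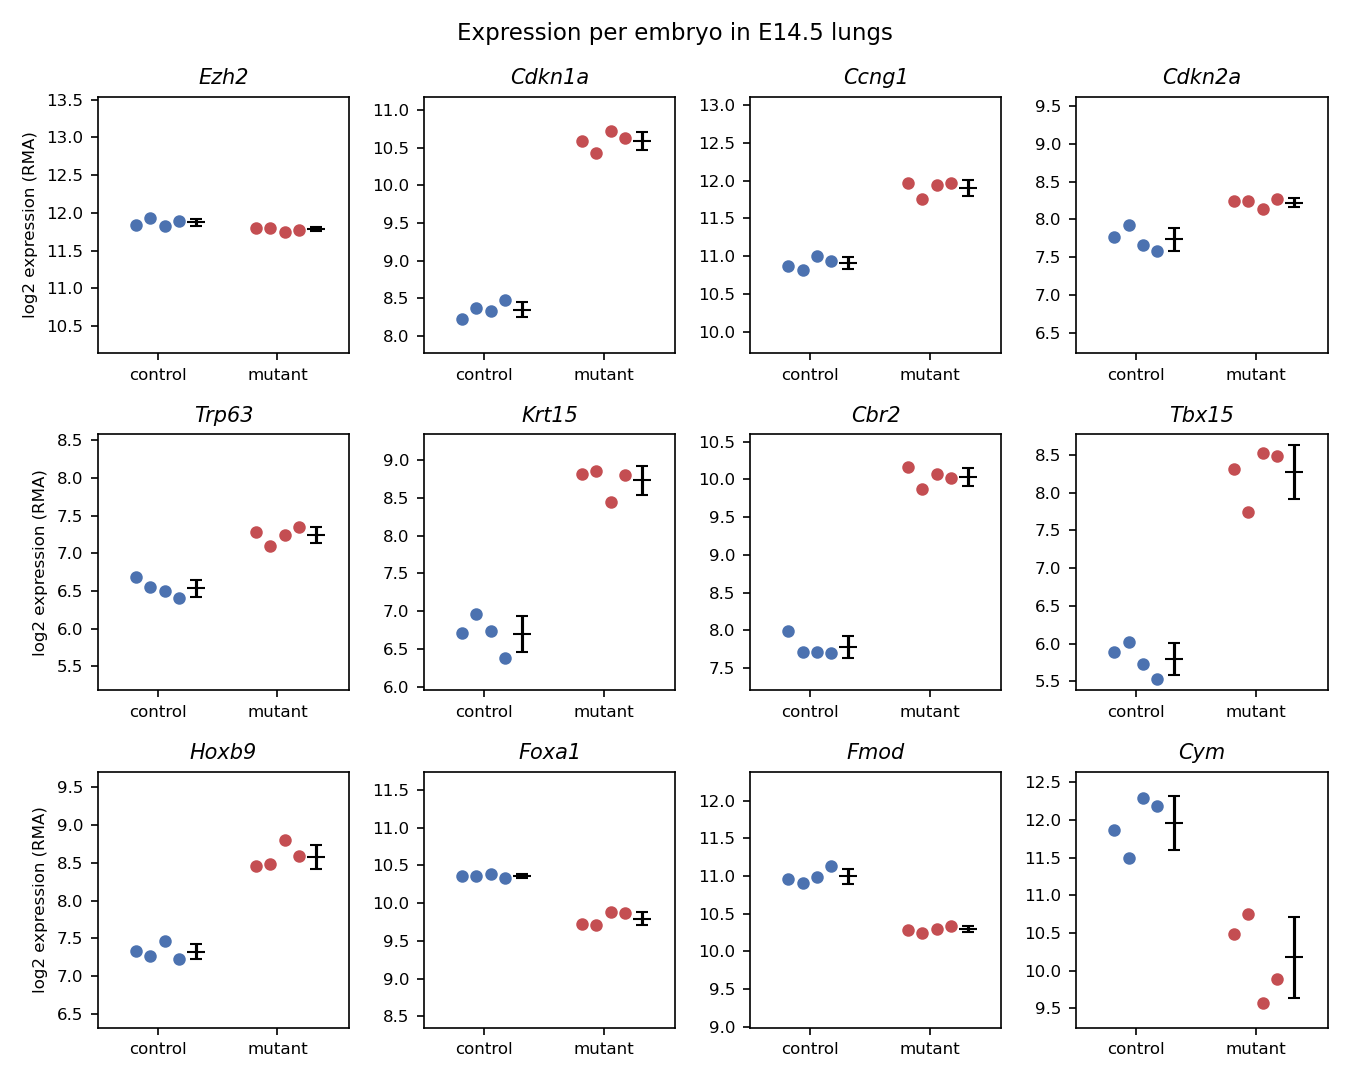
Log2 expression of 12 named genes in each embryo, embryos 1 to 4 from left to right in each group, with the mean and SD of the group beside the points; every panel spans the same range of log2 units. Cdkn1a, Krt15, Cbr2 and Tbx15 lie more than 2 log2 units higher in mutants on average, while Ezh2 differs by 0.09.

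Targets of the transcription factor p53 rose as a group. Of 22 measured members of this list, 9 rose, 0 fell and 13 did not pass, and 12 rose when adjusted over the list alone. Cdkn1a rose by 2.24, Eda2r, a member of the TNF receptor family, by 1.40, Ccng1, the gene of cyclin G1, by 1.00 and Perp, a membrane protein of desmosomes, by 0.96 on the log2 scale. The median log2 change of the list was 0.29 and its adjusted p was 1.54e-18 by camera in limma with Benjamini-Hochberg adjustment. The list stayed past the threshold at an adjusted p of 0.0217 with an estimated correlation. Of 7 CDK inhibitors, 2 rose, Cdkn1a and Cdkn2a, which encodes p16 and p19Arf, with a log2 change of 0.49 ± 0.08 (SE). When adjusted over the list alone 4 rose, the others being Cdkn2b with a log2 change of 0.47 and Cdkn2c with 0.37. Over all genes the adjusted p of Cdkn2b was 0.0549 by limma with Benjamini-Hochberg adjustment. This list had an adjusted p of 0.000695 by camera with Benjamini-Hochberg adjustment, and an adjusted p of 0.0885 with an estimated correlation. Cdkn1c had a log2 change of −0.16 and did not pass. The call of Cdkn2a held in 17 of 24 alternatives. None of 38 proliferation genes passed, with a median log2 change of −0.04.

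Markers of basal cells, the stem cells of the airway, rose. Of 21 measured, 6 rose, 0 fell and 15 did not pass, and 7 rose when adjusted over the list alone. Krt15 rose by 2.04, Dapl1 by 1.28, Krt17 by 1.17 and Trp63, the gene of the basal cell regulator p63, by 0.71 on the log2 scale, while Krt14 had a log2 change of −0.06 and did not pass. The mean log2 change was 0.33 and the median 0.09. The adjusted p was 1.72e-07 by camera in limma with Benjamini-Hochberg adjustment, and the adjusted p was 0.0217 with an estimated correlation. Beside this, 4 markers of oesophagus outside the list were also higher, among them Krt4, a keratin of stratified epithelium, and Pax9, a regulator of foregut endoderm, with log2 changes of 1.22 and 0.78. Proximal airway markers, of which 2 are shared with the basal list and 4 with the secretory list, had 4 genes that rose, Cbr2, Krt15, Anxa8 and Trp63, 0 that fell and 12 that did not pass, with an adjusted p of 2.03e-06 by camera with Benjamini-Hochberg adjustment and an adjusted p of 0.0885 with an estimated correlation. When adjusted over the list alone 7 rose and 1 fell.

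Among 22 markers of club and goblet cells 2 rose, Cbr2 and Lypd2 with log2 changes of 2.26 and 0.43, 1 fell, Cckar, and 19 did not pass. When adjusted over the list alone 7 rose and 2 fell. The adjusted p was 0.000695 by camera with Benjamini-Hochberg adjustment and the adjusted p was 0.447 with an estimated correlation. Cyp2f2 had a log2 change of 0.64 that did not pass, and its second probe set 0.01. The club cell genes Scgb1a1 and Scgb3a2 had log2 changes of 0.01 and 0.06 and did not pass, and the ciliated cell regulator Foxj1 had 0.18 and did not pass. Among 30 distal tip and alveolar markers, Napsa rose by 0.64 on the log2 scale and 0 fell, with 9 higher and 6 lower when adjusted over the list alone. That list did not pass, at an adjusted p of 0.0642 by camera with Benjamini-Hochberg adjustment. It did not pass in 13 of 23 alternatives and passed in the others, with adjusted p from 0.000974 to 0.949 by camera with Benjamini-Hochberg adjustment. Sftpc, the surfactant protein C gene, and Sox9 had log2 changes of 0.08 and −0.10. The airway regulator Sox2 and the lung regulator Nkx2-1 had −0.03 and −0.04. None of these 4 passed. Igf1, at −0.03, did not pass either.

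Hox genes, which pattern the body axis and are textbook targets of Polycomb repression, rose as a group. Of 36 measured, 7 rose, 0 fell and 29 did not pass, and 13 rose when adjusted over the list alone. Hoxb9 rose by 1.26, Hoxa10 by 0.58, Hoxc9 by 0.56 and Hoxb7 by 0.49 on the log2 scale. The log2 change was positive in 34 of the 36, with a median of 0.17. The 7 that rose had mean control log2 values of only 5.99 to 7.42. The Hox genes with the highest control values, 9.31 to 11.09, changed less and did not pass. Picked by level, these were Hoxa5, Hoxa2, Hoxa6, Hoxb5 and Hoxb3, with log2 changes of 0.02, 0.04, 0.16, 0.18 and 0.20. The adjusted p was 9.74e-16 by camera in limma with Benjamini-Hochberg adjustment, and the adjusted p was 0.0217 with an estimated correlation. Among 115 other developmental regulators known as Polycomb targets, 5 rose, among them Tbx15, Tfap2a (log2 change 0.97), Alx1 (0.96) and Pax9 (0.78), 3 fell and 107 did not pass. When adjusted over the list alone 10 rose and 3 fell. The genes that fell, named here after their values were seen, were Irx5, Tbx1 and Irx3, transcription factors with log2 changes of −0.51, −0.46 and −0.35. This list had an adjusted p of 0.000131 by camera with Benjamini-Hochberg adjustment and an adjusted p of 0.577 with an estimated correlation.

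**Figure D2:**
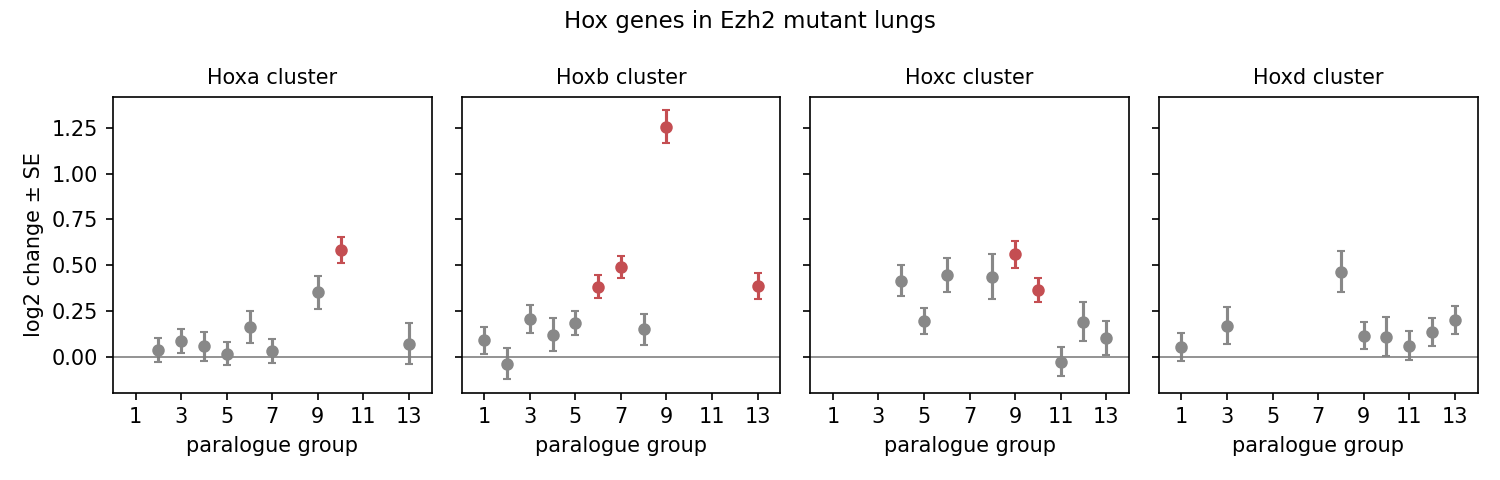
Log2 change between mutant and control lungs of the 36 measured Hox genes by cluster and paralogue group, with error bars of 1 SE; red points passed the test over all genes. Hoxb9, at 1.26, has the highest value, and the 7 genes that passed lie in the a, b and c clusters.

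General epithelial markers moved in both directions. Of 38, Perp and Ovol1, an epithelial transcription factor, rose by 0.96 and 0.41, Foxa1, a transcription factor of lung epithelium, fell by 0.56 ± 0.06 (SE) on the log2 scale, and 35 did not pass. When adjusted over the list alone 3 rose and 7 fell. The median log2 change was −0.07, and the adjusted p was 0.0164 by camera with Benjamini-Hochberg adjustment, in the lower direction, and the adjusted p was 0.745 with an estimated correlation. The median was 0.03 without litter 2. Epcam and Shh had log2 changes of −0.26 and −0.28 that did not pass. Smooth muscle markers fell as a list, with 1 of 24 passing, Cnn1, the gene of calponin, which fell by 0.46 on the log2 scale. When adjusted over the list alone 3 were lower. Cnn1 passed in 12 of 24 alternatives, and the list in 17 of 23 with the preset correlation. The adjusted p was 0.0164 by camera with Benjamini-Hochberg adjustment and the adjusted p was 0.419 with an estimated correlation.

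Further lists passed in the higher direction with few or no members called. Their adjusted p by camera with Benjamini-Hochberg adjustment was 0.0166 for endothelium with 0 of 29 called, 0.0218 for ciliated cells with 0 of 29, 0.0218 for other endoderm lineages with 2 of 41 (Krt4 and Pax9), 0.0287 for mesenchyme with 1 of 39 (Meis2, log2 change 0.30), 0.0442 for IGF signalling with 1 of 20 (Stc1, 0.69) and 0.0442 for mesothelium with 1 of 17 (Upk1b, 0.46). When adjusted over the list alone 0, 0, 3, 1, 1 and 4 genes were higher in these lists. With the preset correlation they passed in 16, 15, 15, 14, 12 and 11 of 23 alternatives in the same order. None of them passed when the correlation was estimated, with an adjusted p of 0.577, 0.447, 0.577, 0.383, 0.447 and 0.447 with an estimated correlation in the same order.

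**Figure D3:**
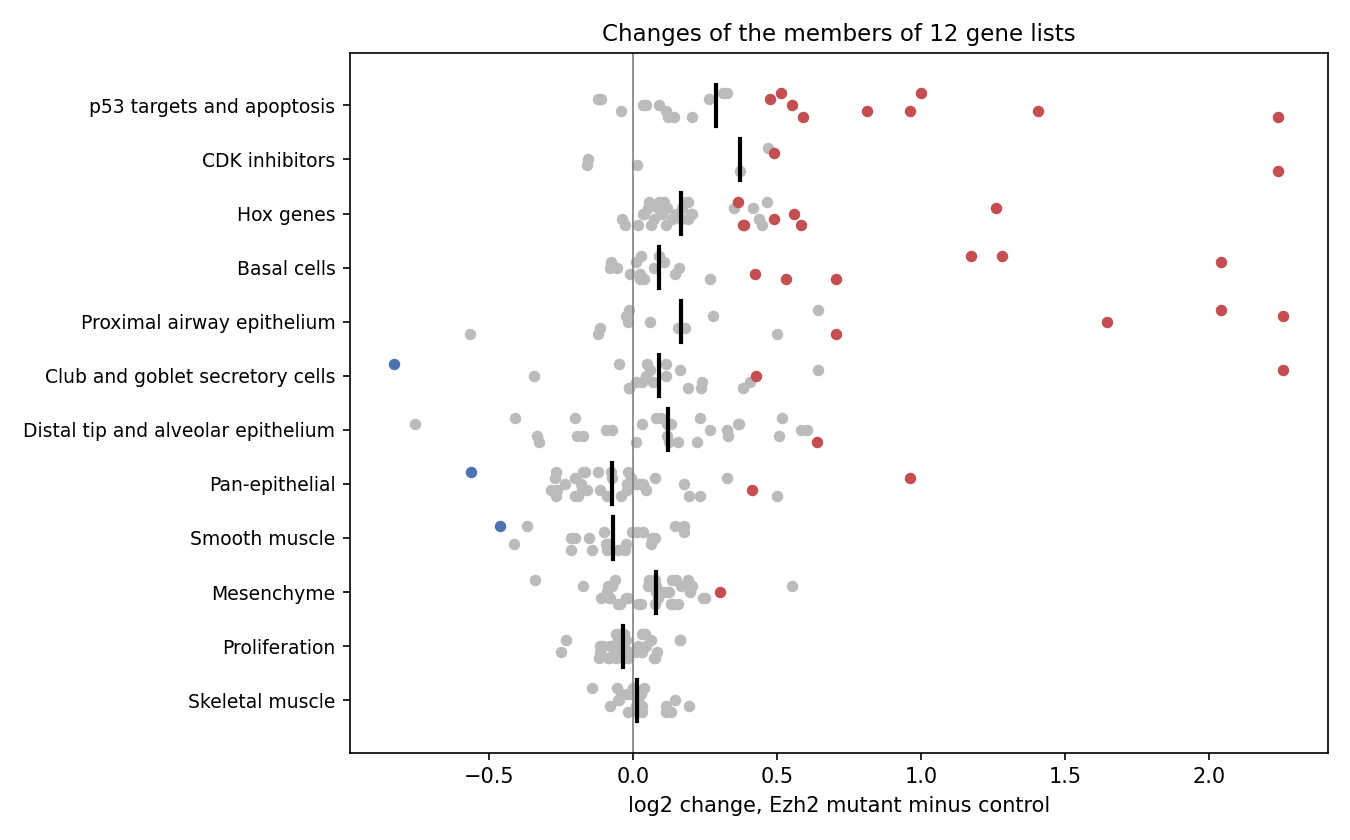
Log2 change of each measured member of 12 of the 40 gene lists, with coloured points for genes that passed the test over all genes (red higher, blue lower), grey points for the others and a black bar at the list median. The p53 target median lies at 0.29 and the skeletal muscle median at 0.01.

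The remaining 25 lists did not pass. In the WNT pathway list, with 30 genes measured, the antagonists Dkk1 and Notum and the transcription factor Lef1 rose by 0.81, 0.36 and 0.33 on the log2 scale, and Lgr5, a receptor for R-spondins, fell by 0.38. The second probe sets of Notum and Lgr5 gave 0.15 and 0.09. Bmpr1b, a BMP receptor, fell by 0.52, Ret, a receptor of neural crest derivatives, by 0.43 and Fmod, a member of the airway cartilage and matrix lists, by 0.70 on the log2 scale. Tgfb2 rose by 0.33 and the Notch ligand Jag2 by 0.42. Most alternatives ended the calls of Lef1, Lgr5, Tgfb2, Jag2 and, in the mesenchyme list, Meis2, which held in 10, 8, 8, 8 and 7 of 24 settings. In the FGF list Etv5 (log2 change −0.33), Fgfr3 (−0.33) and Etv4 (0.23) passed when adjusted over the list alone and not over all genes in the main fit, though each passed over all genes in at least 1 alternative. The lists of neuroendocrine cells, Hedgehog and retinoic acid pathways, imprinted and germline genes, hypoxia, immediate early and heat shock genes, surfactant synthesis, erythroid, myeloid and lymphoid cells, heart and skeletal muscle, thymus and liver, and sex-linked genes had 0 genes passing over all genes. When adjusted over the list alone 2 imprinted genes rose, Asb4 (0.57) and Peg10 (0.35). In the same way 1 germline gene rose, 1 Hedgehog gene fell, and 1 heart gene rose and 1 fell. Median, mean and test differed in sign for FGF (median 0.04, mean −0.01, test lower), airway cartilage (median 0.01, mean −0.004, test higher) and neurons and neural crest (median 0, mean 0.01, test lower).

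Of the 15 lists that passed with the preset correlation, 13 were higher and 2 lower. Those that also passed with an estimated correlation were the lists of p53 targets, Hox genes and basal cells. By the rotation test, 6 lists moved on balance 1 way and 28 changed in either direction, which compares no list with other genes. Among the 6 were the imprinted genes, which did not pass by camera, with an adjusted p of 0.0472 by fry with Benjamini-Hochberg adjustment.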

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

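The tests of sex, handling stress, tissue carry-over, shared probes, epithelial share and of lists with an estimated correlation in other splits were chosen only after the results they bear on had been seen; the counts of genes and of lists in other splits and the litter comparisons were not.

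A single embryo stood far from the rest of its group in 12 of 208 groups of 4 values tested, where chance gives about 1 in 20, or 10.4. Mutant 3 was lowest for Cdkn1c (log2 value 9.35), Krt15 (8.45) and Asb4 (8.62), and mutant 4 was lowest for Anxa8 (7.66) and highest for the CDK inhibitor list mean (0.52). Mutant 2 was lowest for Ccng1 (11.75). Control 3 was highest for Epcam (11.32) and Dapl1 (7.43) and lowest for Lef1 (9.43) and Meis2 (10.37). Control 1 was highest for Cbr2 (7.99) and control 4 for Etv5 (11).

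Among 17824 probe sets without a single gene name, 22 were higher and 6 lower in mutants when all probe sets were tested. Probe set 17278779, at a mean log2 value of 7.07 in controls and 11.18 in mutants, had a log2 change of 4.12 ± 0.12 (SE, n = 4 per group) with an adjusted p of 2.84e-06 by limma with Benjamini-Hochberg adjustment. Its gene was not analysed here. Probe sets 17278757, 17278759, 17278767, 17278769 and 17278858, close to it in number, also rose, by 1.03, 2.49, 0.62, 0.86 and 0.89 on the log2 scale. Whether they lie at 1 locus was not tested, and probe sets without a single gene name did not enter the test of neighbouring genes.

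The 8 embryos can be split into groups of 4 in 35 ways. Only the real split gave as many as 134 genes higher or 55 lower, and the highest count of any other split was 2. This share, 1 of 35, is the smallest these splits can give. It argues against chance for both counts only if embryos are taken as independent, and littermates share a dam. Every other split also mixes the genotypes, which adds any difference between them to the spread within groups. Only 3 splits keep litters whole, too few for a share under 0.05. The other 2 of them called 0 genes, but up to 14 lists with the preset correlation and up to 1 with an estimated one. Between litters the question was therefore left open for genes and lists. For the 15 lists past the threshold with the preset correlation chance cannot be excluded, since 2 of 35 splits gave as many, the real one and one other with 16. With an estimated correlation the real split gave 3 lists and the highest other 1, which 1 of 35 splits reached, again with embryos taken as independent. This last test was added after the count with the preset correlation had failed the same test, so it is weaker evidence than one fixed in advance.

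The p53 target list was higher in mutants. Sex as the source is argued against by the 5 embryos with a high Xist value, among which its median log2 change was 0.303, against 0.286 over all embryos. The controls among them came from litter 2 alone. The list mean differed by at most 0.02 between litters of one genotype, against 0.45 between genotypes. The upper 95% limit of the mean change of the immediate early and heat shock list was 0.151, against a mean change of 0.45 for the p53 list, which argues against handling stress. Loss of Ezh2 may raise these genes, a hypothesis that was not itself tested here, and any feature shared by both mutant litters stays open, as does a change in cell composition.

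The Hox list was higher in mutants. Carry-over of skeletal muscle, heart or nerve tissue as the only source is argued against by the mean change of the Hox list minus that of each tissue list. The smallest lower 95% limit of these was 0.028, for heart. Heart is the weakest case, since 17 of its 22 genes had a positive change, with a mean of 0.065 (95% interval −0.078 to 0.208). Its genes with the highest control values moved both ways. Tnnt2, Nkx2-5 and Myl7 had log2 changes of 0.32, 0.30 and 0.10, and Actc1 and Tnnc1 had −0.48 and −0.07. Tnnt2 and Nkx2-5 lay above the Hox mean of 0.239. Overlapping probes of a single cluster as the only source are argued against by called genes in 3 clusters. That count cannot decide on signal shared within each of several clusters. Sex is argued against by a median of 0.206 among embryos with a high Xist value, again with controls from litter 2 alone. Loss of Polycomb repression is a candidate explanation, a hypothesis that was not itself tested here. Carry-over of other tissues, the rest of the body wall among them, and features shared by both mutant litters were not tested and stay open.

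The basal cell list was higher in mutants. A larger share of epithelium is argued against by the pan-epithelial list, whose mean change had an upper 95% limit of 0.111 against 0.328 for the basal list, and litters of one genotype differed by at most 0.018. Carry-over of oesophagus stays open, since 14 of its markers outside the basal list had a mean log2 change of 0.282 (95% interval 0.169 to 0.395), and 0.162 (0.048 to 0.277) without Krt4 and Pax9, which were known to be higher when the markers were listed. Of the 14, 4 were called, Krt4, Pax9, Trim29 and Fat2, the last 2 named after their values were seen, while Krt13 and Sox2 had −0.01 and −0.03. A basal program in the mutant airway may give the same values, so these data do not call the pattern biological.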

How the results depend on the processing

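The settings without control 3 and mutant 3 and with only high-Xist embryos were chosen after seeing the data. Among 50 called named genes, 26 passed in every setting that held them. Lef1, Lgr5, Tgfb2, Jag2 and Meis2 passed in fewer than 12 of 24, with a highest adjusted p of 0.17, 0.5103, 0.2287, 0.1923 and 0.2287 by limma with Benjamini-Hochberg adjustment. Cnn1, Lypd2 and Napsa passed in 12, 13 and 13 of 24. For Stc1, Bmpr1b, Notum, Adamts18 and Cdkn2a this held in 15, 16, 16, 17 and 17. Over 24 settings 1010 of 1199 values of called genes passed in the same direction, 189 kept the direction without passing and 0 reversed. Of 935 values of named genes that were not called, 78 passed. For called lists the counts, by the direction of the test, were 273, 71 and 1 of 345. The median of the pan-epithelial list was 0.025 without litter 2. The medians of mesothelium and other endoderm lineages also changed sign, with lowest values of −0.034 and −0.004 over 23 settings, against 0.048 and 0.041 in the main fit. Of the lists that were not called, those of distal tip and alveolar cells, heart muscle, proliferation, myeloid and lymphoid cells, hypoxia and imprinted genes stayed so in 13, 19, 19, 20, 21 and 21 of 23 settings and passed in the others. The lists of p53 targets, Hox genes, basal cells, CDK inhibitors and proximal airway passed in all 23 settings of samples, scaling and fit that kept the preset correlation.

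Without the litter block 190 genes were higher and 95 lower. With litter means 65 were higher and 33 lower, of which 63 and 23 were among those of the blocked fit. Leaving out 1 embryo gave 73 to 157 genes higher, 28 to 75 lower, 12 to 15 lists and an Ezh2 log2 change of −0.106 to −0.07; without mutant 4 the counts were 73 and 28, without control 4 they were 89 and 32. Without litter 1, 98 genes were higher and 90 lower, without litter 2 the counts were 175 and 43, without litter 3 they were 112 and 64, and without litter 4 the counts were 75 and 23 with 9 lists. All probe sets gave 99 higher and 34 lower, counted as probe sets. The Xist covariate gave 361 and 313, which held all 134 and 55. An adjusted p under 0.10 gave 195 and 96, and a change of at least 1.5-fold 62 and 19, by construction. Embryos with a high Xist value gave 79 higher and 71 lower. In this setting, without litter 1 and with the Xist covariate the counts were closer to even than 134 and 55. Without litter 2 they were further from it. The high-Xist setting and that without litter 1 share litter 2 as their only controls, so they do not tell sex from control litter. Without control 3 and mutant 3, 8 lists passed. With an estimated correlation 3 lists passed, and 6 by rotation. Fewer samples enter the settings that leave embryos out. Those that leave out a litter or keep only high-Xist embryos also had no litter block, with littermates taken as independent. Otherwise the cause was not tested.

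The replicate numbers do not pair embryos: deviations of same-numbered embryos correlated at −0.272 to 0.027, and 0 controls lay closest to the mutant of their number. With the replicate block, in a fit without the litter block, 140 genes were higher and 55 lower, of which 113 and 43 were shared. Centring moved the median change by −0.0181 and cyclic loess by −0.0043. Lists were not run with the intensity trend or over all probe sets. False calls averaged 9.07% of calls in simulations, whose litter effect may be weaker than that in the data. The litter correlation rests on only 4 litters. Signal over background is not given by these values.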

Other observations

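The comparison of Hox paralogue groups was chosen only after the result was seen; the test of neighbouring genes was not.

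Genes called in the same direction lay beside each other more often than by chance. Among 21994 genes placed in the reference, 10 pairs of neighbours were called in the same direction, against 0.96 on average in 10000 random draws, with a permutation p of 1e-04, the smallest these draws can give. Of these, 5 pairs lay in Hox clusters, and without Hox genes 5 pairs remained, with a permutation p of 0.0017. The pairs, named after their values were seen, included Hoxb7 with Hoxb6, Pou3f3 with 2900092D14Rik, Dcxr with Cbr2 and Trp53cor1 with Cdkn1a among the genes that rose, and Gimap9 with Gimap4 and Herc6 with Pyurf among those that fell. None of the 10 pairs overlap in the reference. Changes that extend over neighbouring genes may account for the 10 pairs, and shared regulation of related genes, which the test does not separate, may too.

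Hox genes of paralogue groups 9 to 13 had a mean log2 change 0.099 above that of groups 1 to 8 (0.297 and 0.197), which did not pass (two-sided exact permutation p 0.0857, n = 4 per group, littermates taken as independent). Without Hoxb9 the difference was 0.03 (exact permutation p 0.429).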
